A study of Xenopus laevis with 16 samples.

How the data were processed

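Gene expression was measured with Affymetrix Xenopus laevis arrays in animal caps, the explanted blastula ectoderm. Per the labels, embryos were injected at the stage of 2 to 4 cells with hormone-inducible Pax3, or with hormone-inducible Pax3 and Zic1, and grown at 15 °C. Caps were explanted at stage 9. Cycloheximide at 0.1 mg/ml was given to the drug groups from stage 10 to 10.5, for 30 min at 23 °C, and dexamethasone for 2 h from stage 10.5, and caps were lysed when sibling embryos reached stage 11.5 to 12. Control caps were neither injected nor treated, and no group had dexamethasone, injection or cycloheximide without the injected factors. Per the labels, RNA was extracted with Trizol and Qiagen columns, and 10 µg was labelled with biotin. There were 16 arrays of 15 biological samples in 5 groups of 3. The replicates were biological, as the labels number them by biological replicate. Of the 4 arrays of Pax3 and Zic1 caps, those named 2.1 and 2.2 carry one biological replicate number and were averaged. Their difference had an SD of 0.183, against 0.517 to 0.759 between biological replicates of a group.

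The deposited values are log2 expression per probe set, a scale taken from the values themselves: array means lie between 4.96 and 4.99. The submitters' processing notes name R 2.14.2; the log base and the steps of background, normalization and summary are not given in the sources used here. No background correction, scaling or filter on level was added. Of 32635 probe sets, the 96 Affymetrix controls were left out and 32539 were tested. The platform's annotation gave 1 gene symbol for 15495 of them, several for 279 and none for 16765. Symbols were looked up by gene identifier in the RefSeq gene table of assembly Xenopus_laevis_v10.1, used for names only, which held 15384 of them and updated 2. The number of arrays limits the precision. No depth applies to arrays.

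Group means of all 5 groups were fitted in one model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust; residual degrees of freedom 10, prior 2.17), with the package data.table, version 1.17.8, for reading. Comparisons were two-sided with Benjamini-Hochberg adjusted p under 0.05 within each comparison and no minimum change. There were 10: Pax3 caps and Pax3 and Zic1 caps against control, without and with cycloheximide; Zic1 added to Pax3, without and with cycloheximide, their mean and their interaction; and cycloheximide against none at the same factors. Overlaps are counts called in one direction in both comparisons, beside n1 × n2 / N and a one-sided Fisher's exact p, and for comparisons with shared controls beside 50 simulations of unchanged groups. The method was tested on simulated data.

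The replicate numbers were checked as pairs after the groups were fixed. With group means removed, all 15 samples correlated best with a sample of their own number; the correlations were 0.43 to 0.86 within a number (median 0.73) and at most -0.1 between numbers (median -0.35). These correlations are across genes, which are not independent replicates. Once group means are removed, positive values within numbers force negative ones between numbers. The negative values are therefore no separate sign of pairing. Pax3 and Zic1 replicate 3 stood apart, at 0.43 to 0.51 with its own number where the lowest of the others was 0.6. What the numbers stand for, such as one batch of embryos, is not given in the sources used here. The replicate number as a block was therefore fitted too (residual degrees of freedom 8, prior 3.4).

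The 24 gene lists were drawn from textbook knowledge: neural plate border, neural crest specifiers, placode and preplacodal, hatching and cement gland, neural plate and neurons, non-neural ectoderm and epidermis, mesoderm and muscle, endoderm, germ plasm and germ cells, pluripotency and blastula factors, the Wnt, BMP, FGF, Notch and retinoic acid pathways, immediate early and cycloheximide superinduced genes, glucocorticoid receptor targets, ribosomal proteins, translation and ribosome biogenesis, unfolded protein and heat shock response, p53 response and apoptosis, cell cycle, adhesion with migration and matrix, and RNA quality with housekeeping. Each gene stood for 1 probe set, the one with the highest mean, and each of the 2 genome copies counted as a gene. Kinases of ribosomal protein S6, which the name pattern of the ribosomal list would also match, were left out of it. Lists share members: 25 of the 37 border genes and 20 of the 42 crest specifiers are on another list too. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one, adjusted over the 24 lists of a comparison, and with fry. Over all comparisons 140 of the list tests passed with the preset correlation and 8 with an estimated one.

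Named genes followed a rule: every probe set of pax3 and zic1; in the comparisons of the factors without the drug and of added Zic1 the 10 largest rises and falls among called probe sets with 1 gene symbol and no overlap between groups, and 5 of each in the other comparisons; up to 4 called members of each list described, or the member with the smallest p where none was called; and the genes of the overlaps. Members of lists named because they moved otherwise than their list, and genes that passed only in the blocked fit, were chosen after their values were seen. Groups, comparisons and their tests, lists, this rule and the alternatives were fixed before the data were examined. The overlap of Pax3 caps with Pax3 and Zic1 caps, both against control without the drug, was added later. Tests of explanations chosen later are named where they are given.

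Alternatives were the replicate block, the replicate as a random block, only the groups compared in the fit, arrayWeights, trend and robust moderation, each array centred on its median, quantile normalization, dim probe sets left out, 1 probe set per symbol, probe sets that match several transcripts left out, arrays 2.1 and 2.2 kept apart or used singly, a minimum change, another probe set of the gene, other set tests, and leaving out each replicate in turn. The RNA samples carry no batch or date label.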

Results

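Animal caps are the ectoderm explanted from the top of a Xenopus laevis blastula; they form epidermis when cultured alone and respond to injected factors. The series used them to ask which genes Pax3 and Zic1 activate, and which of these respond without new protein synthesis. Pax3 and Zic1 are transcription factors of the neural plate border, the strip of ectoderm from which the neural crest arises. The injected forms were hormone-inducible and were switched on with dexamethasone for 2 h. Some caps were given cycloheximide, which blocks translation, for 30 min before that. There were 5 groups with 3 biological replicates each: untreated control caps, Pax3 caps and Pax3 and Zic1 caps, the latter kinds each without and with cycloheximide. The number of arrays limits the precision. Genes carry the ending .L or .S for the 2 copies of this genome. Changes are log2 differences of group means ± SE with n = 3 per group, and adjusted p values are from limma. The replicate numbers turned out to pair the samples across groups, so values from a fit with the replicate number as a block, called the blocked fit, stand beside the results it changes. Every called gene of the rule for named genes moved in its direction in 3 of 3 replicate numbers. For the largest rises and falls this was fixed in advance, since the rule asks for no overlap between groups.

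The injected factors were measured first. A pax3.S probe set was at 1.94 ± 0.39 (mean ± SD, log2) in control caps, 5.91 ± 0.34 in Pax3 caps and 6.90 ± 0.75 in Pax3 and Zic1 caps. With cycloheximide it was at 6.27 ± 0.78 and 6.79 ± 0.84. Its rise over control was 3.96 ± 0.49 in Pax3 caps (adjusted p = 0.00717) and 4.96 in Pax3 and Zic1 caps (adjusted p = 0.00122). 1 pax3.L probe set rose by 3.69 to 5.29 in the same comparisons, and the other pax3.L probe sets passed in none of them. A zic1.S probe set was at 7.14 ± 0.50 in control caps, 8.15 ± 0.54 in Pax3 caps and 9.29 ± 0.50 in Pax3 and Zic1 caps. It rose by 2.16 over control in Pax3 and Zic1 caps (adjusted p = 0.0435), and its change of 1.02 in Pax3 caps did not pass (adjusted p = 0.92, blocked 0.0051). Between Pax3 and Zic1 caps and Pax3 caps it differed by 1.14 without and with the drug, which passed in the blocked fit alone (blocked adjusted p = 0.0066 and 0.00748). The other zic1.S probe set did not follow, at -0.57 and -0.26. Which probe sets detect the injected RNA is not given in the sources used here. The plot of values per sample shows both genes.

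**Figure D1:**
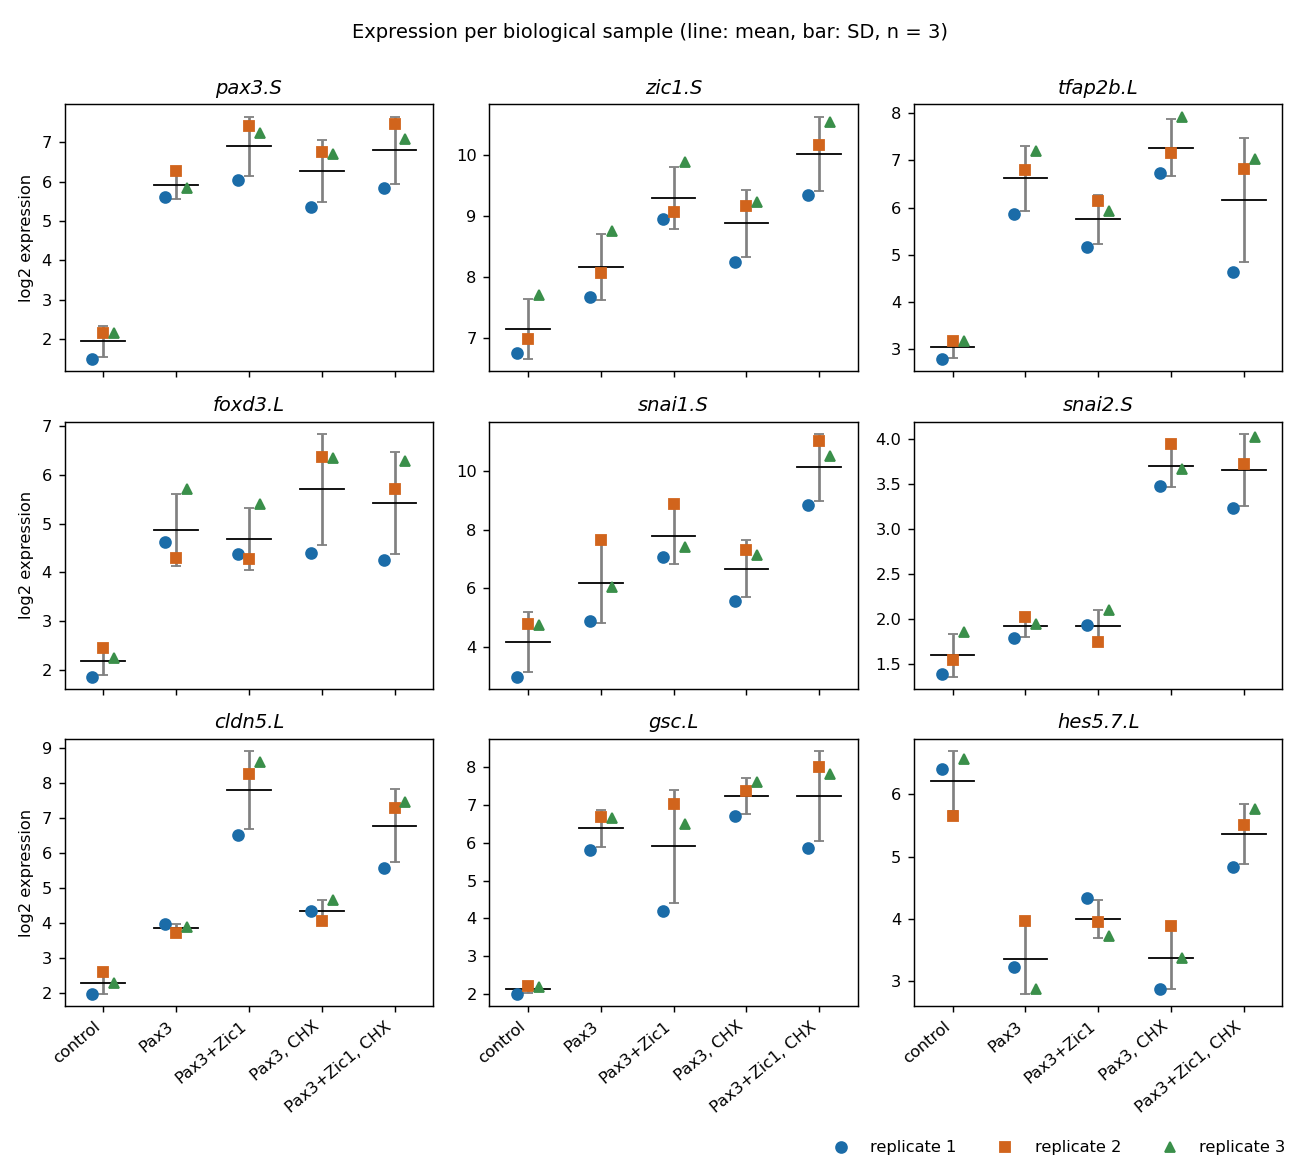
Log2 expression (vertical axis) of 9 genes in each of the 15 biological samples, by group (horizontal axis). Lines are group means, bars are SD (n = 3) and marker shapes are replicate numbers; tfap2b.L had a mean of 3.04 in control caps and 6.62 in Pax3 caps, and cldn5.L 3.86 in Pax3 caps and 7.79 in Pax3 and Zic1 caps.

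Pax3 caps against control caps show what Pax3, with injection and dexamethasone, changed when translation was not blocked. The transcription factor genes with the largest rises included dbx1.S by 4.72 ± 0.53 (adjusted p = 0.00655), irx3.L by 4.45 ± 0.53 (adjusted p = 0.00655) and prdm12.L by 3.86 ± 0.39 (adjusted p = 0.00416). The neural crest specifier tfap2b.L, an AP-2 factor, rose by 3.59 ± 0.57 (adjusted p = 0.0237). Rises also passed for gsc.L, a gene of the organizer, by 4.23 ± 0.68 (adjusted p = 0.0246), gsc.S by 3.05, foxa1.L by 3.93 and gata6.L by 3.02. The Notch target hes5.7.L fell by 2.85 ± 0.36 (adjusted p = 0.00717), and b4galt3.S, a galactosyltransferase gene, fell by 2.13. In all, 93 of 32539 probe sets passed, 72 higher and 21 lower. With the replicate block 695 passed, 273 higher and 422 lower. Among genes with a symbol 34 were higher and 6 lower. Other large rises were those of xa-1.L (5.49), arrdc2.S (4.40) and nrn1.S (4.26), and other falls were those of fut1.S (-1.36), efna4.L (-1.13) and pim1.L (-1.10). Probe sets of one gene did not always move together: another for irx3.L gave 2.32 (adjusted p = 0.203), for arrdc2.S 0.02, for pcdh8.L 0.27 and for nkx6-2.L 0.15.

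By gene list, 1 of the 42 neural crest specifiers measured rose in Pax3 caps (tfap2b.L), 0 fell and 41 did not pass; 2 rose and 1 fell adjusted over the list alone. In the blocked fit 5 rose and 2 fell, among them foxd3.L at 2.69 (adjusted p = 0.146, blocked 0.0048) and snai1.S at 2.02 (adjusted p = 0.938, blocked 0.0043). Of 59 genes of the neural plate and neurons 3 rose and 0 fell (12 and 4 adjusted over the list alone; 10 and 1 blocked), namely prdm12.L, nkx6-2.L and zic2.S. Of 37 neural plate border genes 3 rose and 0 fell (8 and 4 adjusted over the list alone; 5 and 4 blocked), 1 of them the injected pax3.S. For that list the median change was -0.12 and the mean 0.14, and the set test camera did not pass (adjusted p = 0.783). Of 77 genes of the epidermis and other non-neural ectoderm 0 fell and 1, foxa1.L, rose; 8 fell and 2 rose adjusted over the list alone, and 7 fell and 2 rose in the blocked fit, with itln1.L at -2.55 (adjusted p = 0.861, blocked 0.0051). Of 54 BMP pathway genes 0 passed (3 rose and 11 fell adjusted over the list alone; 3 and 6 blocked). Of 30 Notch pathway genes 1 fell and 0 rose (5 and 2 adjusted over the list alone; 4 and 2 blocked).

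Camera with its preset correlation put several of these lists apart from the other genes in Pax3 caps. Crest specifiers were higher (adjusted p = 0.036), as were neural plate genes (9.24e-05) and the 25 placode genes (0.0125, 0 members passing), while epidermal genes (7.58e-16), BMP genes (1.17e-05) and Notch genes (0.000132) were lower. All 6 gave adjusted p = 0.453 with an estimated correlation. Without genes that are on another list too, the BMP and placode calls were lost (camera adjusted p = 0.481 and 0.449). The crest, neural plate, epidermal and Notch lists still passed, at adjusted p of at most 0.00792. Endoderm genes, of which 2 of 38 rose and 0 fell (7 and 0 adjusted over the list alone; 9 and 1 blocked), were higher (adjusted p = 9.84e-05; adjusted p = 0.555 with an estimated correlation). Of 68 mesoderm and muscle genes 3 rose and 0 fell (5 and 0 adjusted over the list alone; 6 and 0 blocked), with a median of -0.02, a mean of 0.18 and adjusted p = 0.126. The 91 ribosomal protein genes were higher as a set by a median of 0.10 (adjusted p = 3.23e-07; adjusted p = 0.537 with an estimated correlation), with 0 members passing in limma. Glucocorticoid receptor targets, which would answer dexamethasone itself, had 0 of 46 members passing (0 rose and 1 fell adjusted over the list alone; 1 and 1 blocked) and adjusted p = 0.76. With cycloheximide 4 of them rose and 0 fell in Pax3 caps (4 and 0 adjusted over the list alone; 7 and 2 blocked) and 3 rose and 0 fell in Pax3 and Zic1 caps (5 and 1; 14 and 1 blocked), at adjusted p = 0.000772 and 1.54e-05 (adjusted p = 0.169 and 0.0954 with an estimated correlation, blocked 0.0738 and 0.0314). In Pax3 caps the drug against none raised the glucocorticoid target list by a mean of 0.35, against 0.47 for the drug group against control. There 3 members rose and 0 fell, and camera gave adjusted p = 0.00138 (0.11 with an estimated correlation). The rise with cycloheximide therefore holds the drug's own effect and cannot be credited to dexamethasone. Cell cycle (111 genes), germ plasm (13), p53 response (32), housekeeping (20), unfolded protein response (50), translation (98), FGF (30), Wnt (66), hatching and cement gland (17) and pluripotency (35) genes had 0 members passing in Pax3 caps without the drug. Adjusted over the list alone, 4 pluripotency genes rose and 6 fell (4 and 1 blocked), and at most 2 genes of any of the others moved in one direction (5 Wnt genes fell in the blocked fit). Their camera tests did not pass either, with adjusted p from 0.0545 to 0.858. That of the hatching list passed in the blocked fit (0.0351), as did that of the translation list (0.0322). Both were lost there with an estimated correlation (adjusted p = 0.316 and 0.616). Leaving out 1 sample gave 17 changed probe sets (without control replicate 3) to 49 (without control replicate 2), so the count of 93 needs all 6 samples.

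Pax3 and Zic1 caps against control caps give the effect of both factors together with that of injection and dexamethasone, which control caps lacked. The largest rises were those of dbx1.S (6.22 ± 0.53, adjusted p = 0.000777) and cldn5.L, a tight junction claudin (5.50 ± 0.53, adjusted p = 0.00104). The BMP antagonists nog.L (3.31 ± 0.55, adjusted p = 0.021), chrd.1.S (2.78 ± 0.45, adjusted p = 0.0189) and nbl1.L (1.55 ± 0.26, adjusted p = 0.0256) rose, and so did prdm12.L by 4.45, gsc.S by 4.40, gata6.L by 4.10, fgf8.L by 2.15 and otx1.L by 1.82. The cement gland gene ag1.L fell by 1.86 ± 0.26 (adjusted p = 0.01), and falls passed for hes5.7.L (-2.21), the Notch ligand dll1.L (-1.17), the ionocyte regulator foxi1.L (-1.07) and the desmosome gene dsp.S (-1.19). In all 160 probe sets passed, 94 higher and 66 lower. With the replicate block 1416 passed, 706 higher and 710 lower. Of the genes with a symbol 51 were higher and 24 lower. Without 1 sample the count ran from 36 (without control replicate 3) to 376 (without Pax3 and Zic1 replicate 1), and was 60 without Pax3 and Zic1 replicate 3, which stood apart from the other samples of its number.

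Among lists, 0 of 42 crest specifiers passed in limma in Pax3 and Zic1 caps, with 3 rising and 0 falling adjusted over the list alone. The nearest, tfap2b.L, was at 2.71 ± 0.57 (adjusted p = 0.068, blocked 0.00101). In the blocked fit 12 rose and 1 fell, among them snai1.S (3.61, adjusted p = 0.0957), foxd3.L (2.49, adjusted p = 0.139, blocked 0.0052), foxd3.S, snai2.L, sox8.L and sox9.L. Of 68 mesoderm and muscle genes 6 rose and 0 fell (9 and 0 adjusted over the list alone; 12 and 0 blocked). Neural plate genes had 4 rises and 1 fall (9 and 3; 10 and 3 blocked), the fall being that of dll1.L. Adhesion and matrix genes had 6 rises and 0 falls of 106 (16 and 5; 19 and 6 blocked), endoderm genes 2 and 0 (5 and 0; 9 and 0 blocked), neural plate border genes 3 and 0 (9 and 3; 10 and 2 blocked), BMP genes 3 and 1 (4 and 10; 5 and 11 blocked), Notch genes 0 and 2 (2 and 9; 2 and 5 blocked) and epidermal genes 0 and 2 of 77 (2 and 17; 3 and 18 blocked), the first figures in brackets being adjusted over the list alone. In camera the crest (adjusted p = 0.0022), neural plate (2.06e-08) and retinoic acid (0.000319) lists were higher and the epidermal list lower (3.17e-14), each at adjusted p = 0.257 with an estimated correlation. The mesoderm (9.6e-07), adhesion (0.00945) and glucocorticoid target (0.0151) lists were higher and the Notch list lower (0.00185), each at adjusted p = 0.393 with an estimated correlation. The endoderm (1.54e-05), FGF (0.000736), Wnt (0.00945) and border (0.0154) lists were higher and the BMP list lower (0.00945), at adjusted p = 0.395 to 0.609 with an estimated correlation. The BMP call was lost without genes that are on another list too (camera adjusted p = 0.457). The 46 glucocorticoid receptor targets had 0 rises and 1 fall, dusp1.L (2 and 1 adjusted over the list alone; 6 and 1 blocked), and the 32 retinoic acid pathway genes had 1 rise, aldh1a2.L, and 1 fall, rarg.S (7 and 3; 7 and 2 blocked).

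Pax3 and Zic1 caps against Pax3 caps, both induced and without cycloheximide, ask what Zic1 adds, though pax3.S also differed between them. cldn5.L rose by 3.93 ± 0.53 (adjusted p = 0.0458), ppp1r13l.L, which encodes the p53 inhibitor iASPP, by 1.79 ± 0.20 (adjusted p = 0.0202), the ephrin receptor gene ephb4.L by 1.45 ± 0.16 (adjusted p = 0.0202) and the aquaporin gene aqp3-a by 1.36 ± 0.17 (adjusted p = 0.0382). These 4 were the genes with a symbol among 6 probe sets that passed, all higher; 0 were lower in limma, and 1589 had an unadjusted p under 0.05 against 1627 by chance (4718 in the blocked fit). With the replicate block 363 passed, 247 higher and 116 lower. They included lmo4.2.L (1.58), nbl1.L (1.52), ccnd1.S (1.27), chrd.1.S (1.41), gata6.S (2.13) and snai1.S (1.59, adjusted p = 1, blocked 0.028), and, lower, foxi1.L (-1.38, adjusted p = 0.0684, blocked 0.0098), irx1.S (-0.99) and sox2.L (-0.94). In the blocked fit pax3.S was higher by 1.15 in 1 probe set and 0.99 in another (blocked adjusted p = 0.0261 and 0.0411). Of the 24 lists only adhesion and matrix had members that passed, cldn5.L and ephb4.L of 106 (8 rose and 4 fell adjusted over the list alone; 6 and 3 blocked), and it was higher in camera (adjusted p = 0.003; adjusted p = 0.7 with an estimated correlation). The mesoderm (2.3e-05), retinoic acid (0.000224), Wnt (0.00228) and FGF (0.00232) lists were higher in camera, each at adjusted p = 0.7 with an estimated correlation, with 0 members passing in limma. Ribosomal proteins were lower (0.000224), and the neural plate and border lists (both 0.0193) and the pluripotency list (0.0454) higher, each at adjusted p = 0.756 with an estimated correlation. Glucocorticoid targets and immediate early genes were higher too (both 0.0418; adjusted p = 0.7 and 0.851 with an estimated correlation). Of the crest specifiers 0 passed (1 and 0 adjusted over the list alone; 4 and 0 blocked; camera adjusted p = 0.334). Without 1 sample the count was 0 (without any replicate of Pax3 or without Pax3 and Zic1 replicate 2) to 68 (without Pax3 and Zic1 replicate 1). In simulated data of this design 37.6% of changes of 1 and 82.2% of changes of 2 on the log2 scale were called, and 83.8% and 98.8% with the block. Per run with 50 changed probe sets of each size, a mean of 0.1 unchanged probe sets was called without the block and 7.7 with it.

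The same comparison with cycloheximide in both groups is matched for the drug and asks what Zic1 adds while translation is blocked. glipr2.S rose by 4.10 ± 0.56 (adjusted p = 0.0337), inhbb.L, an activin subunit gene, by 3.29 ± 0.47 (adjusted p = 0.0461), and the eye field gene rax.L by 2.93 ± 0.31 (adjusted p = 0.00666). celf3.S (2.11), ppp1r13l.L (1.93) and ephb4.L (1.13) rose too, and irx1.S fell by 1.5 ± 0.16 (adjusted p = 0.00666). Another rax.L probe set gave 3.35 and did not pass (adjusted p = 0.212). In all 11 probe sets passed, 9 higher and 2 lower, and with the block 242, of which 177 were higher and 65 lower. snai1.S was at 3.46 (adjusted p = 0.334, blocked 0.000644), and foxf1.L (3.25), myod1.S (2.71), cldn5.L (2.42) and dkk1.S (2.03) passed in the blocked fit alone. Of the mesoderm and muscle genes 0 of 68 passed (6 rose and 1 fell adjusted over the list alone; 5 and 0 blocked). That list was higher in camera (adjusted p = 3.79e-13), as were the endoderm (9.32e-06), FGF (1.3e-05), adhesion and retinoic acid (both 0.00033) lists, each at adjusted p = 0.344 with an estimated correlation. Also higher were the Wnt (0.000868), neural plate (0.00528), Notch (0.026), glucocorticoid target and immediate early (both 0.0293) and p53 response (0.0469) lists. The translation (0.00966), ribosomal protein (0.0127), epidermal (0.0147) and placode (0.0183) lists were lower. All of these were at adjusted p = 0.344 to 0.64 with an estimated correlation. irx1.S was the 1 member of the border and placode lists that passed, and ephb4.L that of the adhesion list (6 rose and 1 fell adjusted over the list alone; 8 and 0 blocked). Fits without 1 sample gave 4 (without Pax3 with cycloheximide replicate 1, or Pax3 and Zic1 with cycloheximide replicate 2) to 47 (without Pax3 and Zic1 with cycloheximide replicate 1).

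Whether the Zic1 effect depended on the drug was tested as an interaction. In limma 0 of 32539 probe sets passed, without and with the block. An unadjusted p under 0.05 was reached by 193 (778 with the block), against 1627 by chance. Both counts lie below chance, and the simulated data did not cover the interaction. The 0 therefore does not show that the Zic1 effect was the same without and with the drug. The mean Zic1 effect over both arms, 6 samples against 6, passed at 164 probe sets, 122 higher and 42 lower; with the block 1298 passed, 823 higher and 475 lower. ephb4.L rose by 1.29 ± 0.12 (adjusted p = 0.00114), glipr2.S by 3.98 ± 0.39 (adjusted p = 0.00227), cldn5.L by 3.18 ± 0.38 (adjusted p = 0.00577) and the mesoderm gene foxf1.L by 2.69 ± 0.46 (adjusted p = 0.0268). Border gene lmo4.2.L rose by 1.51 ± 0.25 (adjusted p = 0.0219) and ccnd1.S by 1.11 ± 0.14 (adjusted p = 0.00617). irx1.S fell by 1.25 ± 0.11 (adjusted p = 0.00114), and falls passed for hes5.1.S (-1.51), nrn1.S (-2.34) and ag1.L (-1.06), while hes5.7.L rose by 1.31. snai1.S did not pass at 2.52 (adjusted p = 0.0978, blocked 0.00016). Of the adhesion genes 6 rose and 3 fell (9 and 3 adjusted over the list alone; 15 and 4 blocked), the falls being those of ephb3.S, cxcr4.S and cxcr4.L, and of the mesoderm and muscle genes 3 rose and 0 fell (11 and 1; 11 and 0 blocked). Of the crest specifiers 1, lmo4.2.L, rose and 0 fell (3 and 0; 7 and 2 blocked), and of the retinoic acid genes 1, ptgds.S, rose by 2.56 (6 and 0; 7 and 0 blocked). Camera put the mesoderm (adjusted p = 1.15e-10), adhesion (0.000312) and retinoic acid (3.52e-05) lists higher, each at adjusted p = 0.404 with an estimated correlation. 1 of the 20 housekeeping genes, tubb4b.S, rose by 1.15. Leaving out 1 sample of either arm gave 51 (without Pax3 with cycloheximide replicate 1) to 311 (without Pax3 and Zic1 replicate 1).

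The Zic1 comparisons without and with cycloheximide share no arrays, but both use the spread of each probe set from the one fit. Probe sets with a small spread are called more readily in both. The counts for independent lists and the Fisher's exact p can therefore overstate the sharing. 2 probe sets, those of ppp1r13l.L and ephb4.L, were higher in both (6 and 9 called; one-sided Fisher's exact p = 1.02e-06), and 0 were lower in both in limma, where 0 and 2 were called. With the block 87 were higher in both against 1.34 for independent lists, and 28 lower in both against 0.23. Leaving out 1 sample gave 0 to 9 shared rises, the 9 without Pax3 and Zic1 replicate 1 and the 0 without any replicate of Pax3, Pax3 and Zic1 replicate 2 or Pax3 with cycloheximide replicate 3.

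**Figure D2:**
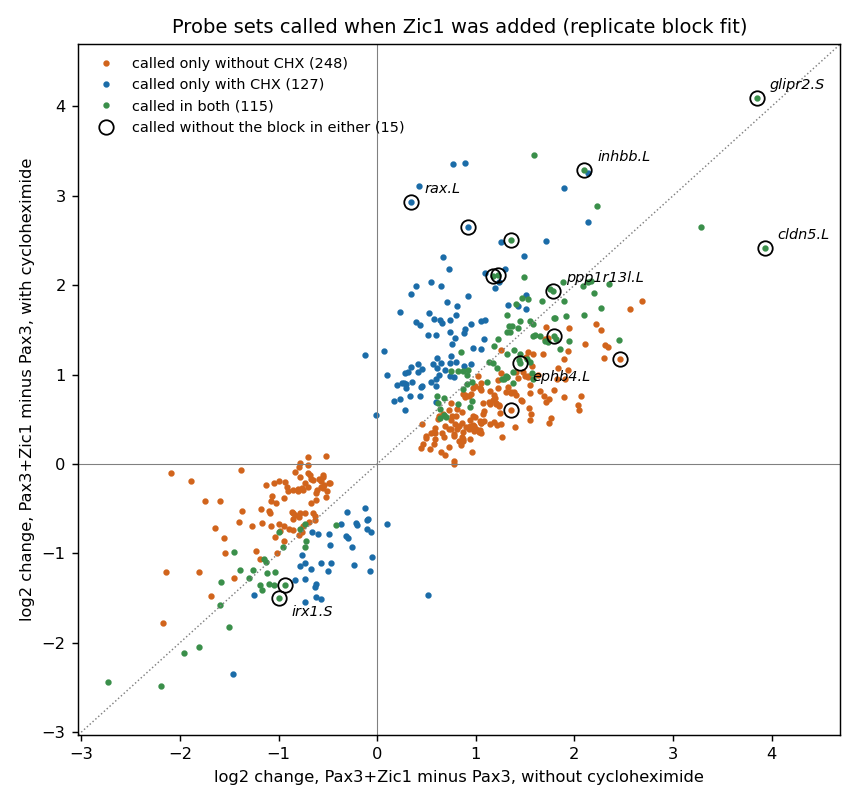
Log2 change between Pax3 and Zic1 caps and Pax3 caps, without cycloheximide (horizontal axis) and with it (vertical axis), for the probe sets called in the blocked fit. 363 were called without the drug and 242 with it; 87 were higher and 28 lower in both, and circles mark the 15 called without the block.

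With cycloheximide, Pax3 caps and Pax3 and Zic1 caps were compared with untreated controls to ask which genes the factors change without new protein. No group had the drug without the factors, so these comparisons hold the drug's own effect as well. Crest specifiers rose in Pax3 caps: tfap2b.L by 4.24 ± 0.57 (adjusted p = 0.00221), foxd3.L by 3.52 ± 0.62 (adjusted p = 0.00961) and snai2.S by 2.09 ± 0.20 (adjusted p = 0.000288). In Pax3 and Zic1 caps snai1.S rose by 5.95 ± 0.82 (adjusted p = 0.00144), foxd3.L by 3.23 ± 0.62 (adjusted p = 0.0101), tfap2b.L by 3.12 ± 0.57 (adjusted p = 0.00779) and snai2.L by 3.09. hes7.1.L rose by 5.60 and 6.38, gsc.L by 5.08 in both, nkx6-2.L by 4.13 and 5.15, and the endoderm gene sox17b.1.S by 5.94 and 4.21. Falls passed for the cement gland gene ag1.S (-4.47 and -4.95), the epidermal lectin itln1.L (-4.27 and -4.72) and otogl2.L (-4.17 and -5.34). In Pax3 caps 822 probe sets passed, 418 higher and 404 lower (203 and 162 genes with a symbol), and with the block 4836, 2562 higher and 2274 lower. In Pax3 and Zic1 caps 1483 passed, 719 higher and 764 lower (357 and 318 genes with a symbol), and with the block 6159, 2978 higher and 3181 lower. Fits without 1 sample gave 396 (without control replicate 3) to 539 (without Pax3 with cycloheximide replicate 2) and 893 (without Pax3 and Zic1 with cycloheximide replicate 3) to 1097.

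In these comparisons 4 of 42 crest specifiers rose and 0 fell in Pax3 caps (12 and 0 adjusted over the list alone; 15 and 2 blocked), and 6 rose and 1, myb.S (-1.26), fell in Pax3 and Zic1 caps (9 and 1; 16 and 1 blocked). The list was higher in camera at adjusted p = 3.97e-08 and 7.12e-08, and held with an estimated correlation at adjusted p = 0.0384 and 0.0244. The drug against none at the same factors also raised this list, by a mean of 0.40 in Pax3 caps and 0.35 in Pax3 and Zic1 caps against 0.75 and 0.84 here (adjusted p = 9.89e-07 and 0.000363; adjusted p = 0.0445 and 0.121 with an estimated correlation, blocked 0.0715 and 0.123). There 1 member rose and 0 fell in each (3 and 0, then 2 and 0 adjusted over the list alone; 7 and 0, then 8 and 2 blocked). Neural plate genes had 12 rises and 0 falls in Pax3 caps and 15 rises and 1 fall in Pax3 and Zic1 caps, the fall being that of ncam1.S (19 and 1, then 20 and 1 adjusted over the list alone; 22 and 2, then 28 and 2 blocked). Mesoderm and muscle genes had 7 and 13 rises and 0 falls (9 and 15; 11 and 21 blocked), and endoderm genes 7 and 11 rises and 0 falls (10 and 16; 12 and 16 blocked). Epidermal genes had 11 falls and 3 rises in Pax3 caps and 19 falls and 4 rises in Pax3 and Zic1 caps (25 and 4 in both adjusted over the list alone; 27 and 5, then 28 and 5 blocked). krt12.5.S fell (-2.77 and -4.06) and so did krt70.L in Pax3 and Zic1 caps (-4.21), whereas foxa1.L (4.09 and 3.56), foxi1.L (1.93 and 1.86) and cyp26a1.S (1.87 and 3.06) of that list rose. For the neural plate, endoderm, mesoderm and epidermal lists camera passed in both comparisons at the preset correlation, with adjusted p from 2.54e-14 to 0.0188. All of these calls were lost at adjusted p = 0.0808 to 0.493 with an estimated correlation. The blocked fit gave 0.0342 with an estimated correlation for neural plate genes in Pax3 and Zic1 caps, and 0.0552 with the preset one for mesoderm in Pax3 caps. Wnt pathway genes had 6 rises and 1 fall, then 11 rises and 1 fall, the fall being that of dvl3.L (10 and 2, then 17 and 2 adjusted over the list alone; 14 and 4, then 22 and 4 blocked), with axin2.L at 1.5 and 1.97. p53 response genes had 4 and 7 rises and 0 falls (6 and 8; 8 and 11 blocked) and were higher as a set with an estimated correlation too (adjusted p = 0.0406 and 0.0244, blocked 0.141 and 0.0765). The drug at the same factors raised that set by a mean of 0.51 and 0.67, against 0.53 and 0.68 here, with 3 and 4 rises and 0 falls (4 and 9 adjusted over the list alone; 8 and 12 blocked) and adjusted p = 0.0445 and 0.0372 with an estimated correlation (blocked 0.0901 and 0.123).

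The effect of cycloheximide itself was measured in caps with the same factors. hes7.1.L rose by 3.94 ± 0.46 in Pax3 caps (adjusted p = 0.0027) and 4.69 in Pax3 and Zic1 caps (adjusted p = 0.000593), gadd45g.L by 3.39 and 4.18, the endoderm gene sox17b.1.L by 3.06 and 3.75, and snai2.S by 1.77 ± 0.20 (adjusted p = 0.00254) and 1.73. Falls passed for ostc.L (-3.07 and -3.52), pdia4.L (-1.68 and -1.91) and herpud1.S (-1.35 and -1.44). In Pax3 caps 283 probe sets passed, 164 higher and 119 lower (87 and 51 genes with a symbol), and with the block 3412, 1778 higher and 1634 lower. In Pax3 and Zic1 caps 517 passed, 274 higher and 243 lower (147 and 121 genes with a symbol), and with the block 5344, 2595 higher and 2749 lower. Of 68 immediate early genes, which cycloheximide is known to superinduce, 8 and 10 rose and 0 fell (19 and 1, then 14 and 1 adjusted over the list alone; 27 and 2, then 22 and 3 blocked), among them nfkbia.L at 1.61 and 1.81. Camera gave adjusted p = 1.03e-15 and 2.29e-11, and adjusted p = 0.0916 and 0.223 with an estimated correlation, which passed in the blocked fit (0.00329 and 0.0102). Of 50 unfolded protein and heat shock genes 5 and 8 fell and 2 rose, ddit3.L at 1.47 and 0.79 and sesn2.S at 1.29 and 1.32 (18 fell and 3 rose, then 17 and 2 adjusted over the list alone; 19 and 2, then 21 and 2 blocked). The set was lower at adjusted p = 5.52e-09 and 1.38e-07 (adjusted p = 0.071 and 0.121 with an estimated correlation). Of 30 Notch genes 5 and 8 rose and 0 fell (10 and 1, then 13 and 1 adjusted over the list alone; 10 and 0, then 14 and 1 blocked), with adjusted p = 0.0445 and 0.0606 with an estimated correlation (blocked 0.0901 and 0.123). The 91 ribosomal protein genes had 0 members passing in Pax3 caps and 1 fall in Pax3 and Zic1 caps, that of rpl8.S (-0.50), and 23 and 28 falls with the block; the set was lower at adjusted p = 4.63e-22 and 1.92e-13 (adjusted p = 0.0919 and 0.223 with an estimated correlation). Fits that left out 1 sample gave 89 (without Pax3 replicate 3) to 167 (without Pax3 replicate 2) and 201 (without Pax3 and Zic1 with cycloheximide replicate 3) to 1308 (without Pax3 and Zic1 replicate 1).

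Under cycloheximide at the same factors 5 and 4 neural plate genes rose and 0 fell (8 and 12 rose adjusted over the list alone; 15 and 17 blocked), as did 5 and 6 Wnt genes (10 and 7; 13 and 11 blocked) and 3 and 3 border genes (10 and 7; 11 and 8 blocked). The bracketed counts of these lists are rises only, and in the blocked fit of Pax3 caps 1 Wnt gene fell. The neural plate, Wnt and border lists were higher in camera with adjusted p from 4.43e-09 to 0.004, and adjusted p = 0.11 to 0.301 with an estimated correlation. Of 111 cell cycle genes 3 rose and 1 fell in Pax3 caps and 3 rose and 2 fell in Pax3 and Zic1 caps (3 and 1, then 3 and 3 adjusted over the list alone; 20 and 2, then 21 and 7 blocked), with rbl1.L at 1.86 in Pax3 caps and cdk1.S at -0.72 and -1.08. That list was higher in camera at adjusted p = 1.99e-05 and 0.000177 (adjusted p = 0.138 and 0.258 with an estimated correlation). Of 98 translation genes 1 and 2 rose and 0 fell (1 and 2 rose adjusted over the list alone; 2 rose and 9 fell, then 3 and 17 blocked), and as a set they were lower in camera (adjusted p = 0.000746 and 0.000398; adjusted p = 0.138 and 0.223 with an estimated correlation). The hatching and cement gland list had 2 rises and 2 falls in Pax3 caps, with ag1.S at -3.20 and klf17.1.S at 2.11 (2 and 4 adjusted over the list alone; 2 and 5 blocked). The 13 germ plasm genes had 0 members passing in each of the 10 comparisons in limma. The array's gapdh probe sets, whose 3' and 5' ends report RNA integrity, differed between ends by 0.69 ± 0.08 (SD) in control caps, 0.74 ± 0.16 in Pax3 caps, 0.74 ± 0.19 in Pax3 and Zic1 caps, and 0.76 ± 0.14 and 0.93 ± 0.13 with cycloheximide. Of the 20 RNA quality and housekeeping genes 0 passed under the drug in limma (0 adjusted over the list alone as well), and 8 and 6 fell in the blocked fit. That list was lower with the drug in Pax3 caps (adjusted p = 0.00532; adjusted p = 0.11 with an estimated correlation) and did not pass in Pax3 and Zic1 caps (adjusted p = 0.0544, blocked 0.0176).

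**Figure D3:**
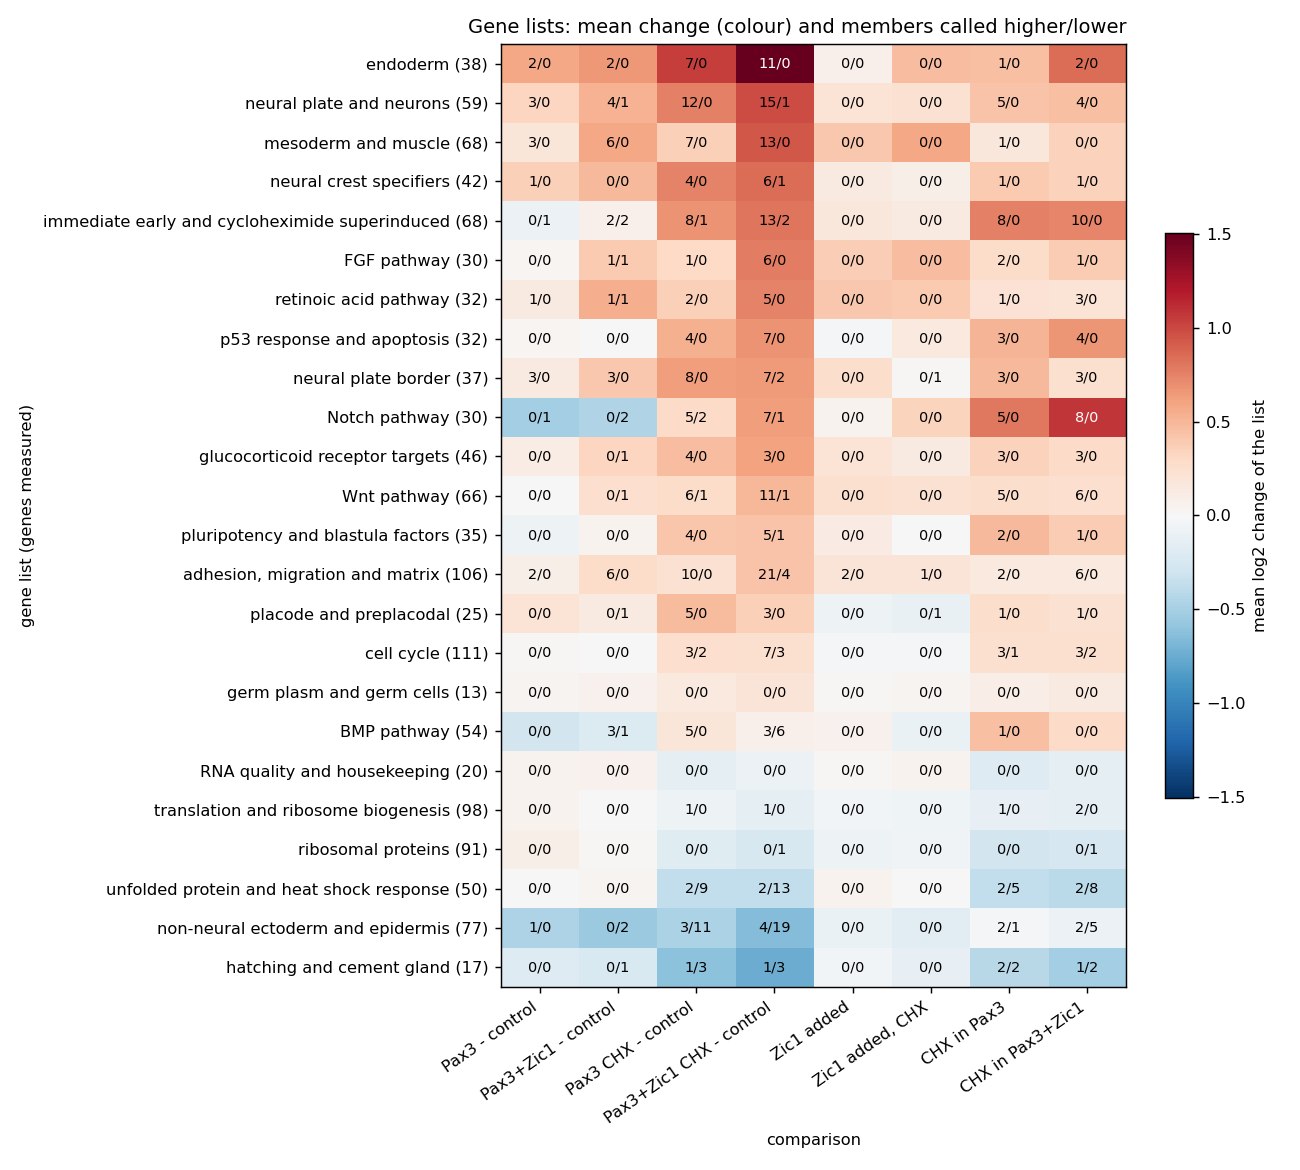
Mean log2 change of the 24 gene lists (vertical axis) in 8 comparisons (horizontal axis), as colour, with the number of members called higher and lower printed in each field. Among the crest specifiers 1 member was higher and 0 lower in Pax3 caps against control, and 6 were higher and 1 lower in Pax3 and Zic1 caps with cycloheximide.

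The sets of genes changed against control without and with cycloheximide were compared to see how many changes were shared. In Pax3 and Zic1 caps 84 of the 94 probe sets higher without the drug were also among the 719 higher with it, against 2.08 for independent lists, and 42 of 66 lower ones among 764, against 1.55. In Pax3 caps 58 of 72 higher ones were among the 418, against 0.92, and 14 of 21 lower ones among the 404, against 0.26. The blocked overlaps were 524 and 472 in Pax3 and Zic1 caps, against 64.6 and 69.4, and 218 and 269 in Pax3 caps, against 21.5 and 29.5. Pax3 caps and Pax3 and Zic1 caps without the drug shared 36 rises, against 0.21, and 14 falls, against 0.04 (173 and 285 with the block, against 5.92 and 9.21). This last overlap was not among those planned. All these comparisons use the same 3 control arrays, so part of each overlap may come from the shared controls. In 50 simulations no group was changed, and the groups shared simulated controls without the pairing by replicate number. There 0 probe sets were called in both, and 184 to 185 shared an unadjusted p under 0.05 where 681, 336 and 271 did in the data. With nothing changed few calls could arise, so the 0 does not measure the part of the shared controls. Of the 719 probe sets higher in Pax3 and Zic1 caps with cycloheximide, 214 were also higher with than without the drug at the same factors and 425 were called in neither way; of the 418 in Pax3 caps these were 116 and 246. Without 1 sample the shared rises were 28 (without control replicate 3) to 150 (without Pax3 and Zic1 replicate 1) in Pax3 and Zic1 caps and 15 (without control replicate 3) to 45 in Pax3 caps.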

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

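No test in this part was chosen after its result was seen. The 4 results here are differences between the Zic1 effect with cycloheximide and the Zic1 effect without it, tested for gene lists with camera on the interaction at the preset correlation. The neural plate border list was lower in the interaction (adjusted p = 0.00172) and the BMP pathway list was lower too (adjusted p = 0.0382). The endoderm list was higher (adjusted p = 0.00856), and so was the p53 response and apoptosis list (adjusted p = 0.0382). With an estimated correlation each of the 4 gave adjusted p = 0.969, so these differences rest on the assumed correlation between genes. No single probe set passed the interaction: 0 of 32539 in limma, with 193 at an unadjusted p under 0.05. No explanation was tested for them.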

How the results depend on the processing

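No alternative here was chosen after the result was seen. Of 1054 named gene values 373 passed, and all 373 kept their direction under every alternative but another probe set of the gene; 123 kept the threshold too. The replicate block and the random block (consensus correlation 0.526) kept all 373. Fitting only the groups compared lost 226, centring each array on its median 19, quantile normalization 17, array 2.1 alone 11, arrayWeights 4, trend and robust moderation 3, array 2.2 alone 2 and leaving out dim probe sets 2 of 311. Leaving out 1 replicate lost 838 of 2394. Of 240 list tests 132 weakened with an estimated correlation and 99 with fry, and the lists called went from 140 to 8 and 44. Without genes that are on another list too, 25 weakened, 6 became stronger and 6 reversed, and 117 were called. The interaction stayed at 0 in every alternative run. A minimum change of 1 on log2 kept the counts within 1.5 times.

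Counts beyond 1.5 times the reported one follow by setting; except for fewer samples or fewer probe sets tested, the cause was not tested. The order is Pax3 against control (93 reported), Pax3 and Zic1 against control (160), the same with cycloheximide (822 and 1483), Zic1 added without and with cycloheximide (6 and 11), the mean Zic1 effect (164), and cycloheximide in Pax3 caps (283) and in Pax3 and Zic1 caps (517). The replicate block gave 695, 1416, 4836, 6159, 363, 242, 1298, 3412 and 5344, and the random block 632, 1192, 3920, 5319, 324, 233, 1094, 2582 and 4334. Only the groups compared gave 29, 11, 467, 617, 0, 0, 80, 0 and 20 with fewer samples. One probe set per gene symbol gave 36, 68, 336, 632, 11, 6, 73, 120 and 271 over fewer probe sets. arrayWeights gave 162 and 1267 for Pax3 without and with the drug, 27 and 23 for added Zic1, 307 for its mean and 517 for the drug in Pax3 caps. Keeping arrays 2.1 and 2.2 apart, which counts 1 biological replicate as 2, gave 347 for Pax3 and Zic1, 55 for Zic1 added, 302 for the mean and 1082 for the drug in Pax3 and Zic1 caps. For Zic1 added, quantile normalization gave 11, trend and robust moderation 10 and leaving out probe sets that match several transcripts 3. Leaving out dim probe sets gave 4 for Zic1 added in cycloheximide and 72 for the mean.

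Of the shared rises, 2 for Zic1 added in both arms became 87 with the replicate block, 74 with the random block, 0 with only the groups compared, 1 with centred arrays, 4 with arrayWeights and 1 with array 2.1 alone. The 84 of Pax3 and Zic1 against control became 524, 451, 10, 143 with arrays 2.1 and 2.2 apart and 44 with one probe set per symbol. The 58 of Pax3 against control became 218, 207, 24 and 22 with one probe set per symbol.

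Leaving out 1 sample gave 17 to 49 for Pax3 against control: without control replicates 1, 2 and 3 the counts were 47, 49 and 17, and without Pax3 replicates 1, 2 and 3 they were 22, 46 and 38. For Pax3 and Zic1 against control (36 to 376) they were 67, 66 and 36 without the controls and 376, 42 and 60 without the Pax3 and Zic1 replicates. For Pax3 in cycloheximide (396 to 539) they were 535, 520 and 396 without the controls and 420, 539 and 465 without the treated replicates. For both factors in cycloheximide (893 to 1097) they were 962, 935 and 908 without the controls and 893 without treated replicate 3. Zic1 added gave 0 without Pax3 replicate 1, 2 or 3 or Pax3 and Zic1 replicate 2, and 68 without Pax3 and Zic1 replicate 1. In cycloheximide it gave 4 and 7 without Pax3 replicates 1 and 3, and 47 and 4 without Pax3 and Zic1 replicates 1 and 2. The drug in Pax3 caps (89 to 167) gave 109, 135 and 136 without drug replicates 1, 2 and 3 and 134, 167 and 89 without the others. In Pax3 and Zic1 caps (201 to 1308) it gave 321 and 201 without drug replicates 1 and 3, and 1308, 249 and 225 without the others. The mean Zic1 effect (51 to 311) gave 73, 73 and 64 without Pax3 replicates 1, 2 and 3, 311 and 60 without Pax3 and Zic1 replicates 1 and 2, 51, 99 and 82 without Pax3 replicates in the drug, and 75 and 79 without Pax3 and Zic1 replicates 2 and 3 in the drug. The interaction stayed at 0.

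Shared rises for Zic1 added (0 to 9) were 9 without Pax3 and Zic1 replicate 1, 4 without replicate 1 of that group in the drug, and 1 without replicate 2 or 3 of it or Pax3 replicate 1 or 2 in the drug. They were 0 without Pax3 replicate 1, 2 or 3, Pax3 replicate 3 in the drug or Pax3 and Zic1 replicate 2. Those of Pax3 and Zic1 against control (28 to 150) were 34, 39 and 28 without the controls and 150, 31 and 39 without Pax3 and Zic1 replicates 1, 2 and 3. Those of Pax3 (15 to 45) were 28, 36 and 15 without the controls and 20, 27 and 33 without Pax3 replicates. Each such fit pools the spread over all groups. Pax3 and Zic1 replicate 3 had the lowest array weight, 0.45, and control replicate 2 the highest, 1.7.

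Another probe set of the gene went the same way and passed for 96 of 227 called values, did not pass for 99 and reversed for 32; the cause was not tested. For pax3.L the reversed values were -0.19, -0.34, -0.34 and -0.27 in Pax3 caps, -0.92 in Pax3 and Zic1 caps, and -0.12, -0.35, -0.71 and -0.06, -0.27, -0.69 with cycloheximide. For arrdc2.S they were -0.17 in Pax3 and Zic1 caps and, with cycloheximide, -0.15 there and -0.07 in Pax3 caps. For the drug in Pax3 caps sbk1l.L had -0.41, -0.38, -0.13, -0.2, -0.13, -0.73 and -0.15, and cirbp.S 0.21 and 0.01; in Pax3 and Zic1 caps krt7.L had 0.27. pmm2.L had 0.27 and 0.21 in Pax3 and Zic1 caps and 0.06 and 0.08 with cycloheximide. aldh1a2.L had -0.01 in Pax3 caps and -0.86 and -0.6 with cycloheximide, where cyp26a1.S had -0.09.

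List tests in limma reversed, without passing, when genes on another list too were left out: pluripotency at adjusted p = 0.536 and 0.942 against control in cycloheximide (Pax3, then both factors) and 0.864 for the drug in Pax3 and Zic1 caps, and immediate early genes at adjusted p = 0.98, 0.933 and 0.983 for Zic1 added, the same in the drug, and their mean. With every probe set of each gene the placode list reversed in limma at adjusted p = 0.935 for Zic1 added in the drug. The cause was not tested. Signal over background limits the dim genes, since no detection calls were used.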

Other observations

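The tests of mesendoderm cells and of the drug in this part were chosen only after the result was seen.

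Some genes, picked after their values were seen and tested as no group, passed in the blocked fit without passing in the fit without it. In Pax3 caps hes5.5.S (-2.56), hes5.6.L (-2.56) and hes5.2.L (-1.89) were lower, while hes7.1.L (1.66), six3.L (1.47) and sox1.S (1.56) were higher. Of the glucocorticoid receptor targets, cebpb.L was higher in Pax3 caps (2.42) and in Pax3 and Zic1 caps (2.65), cebpd.L was higher in Pax3 and Zic1 caps (2.23), and sgk1.L, at 1.76 in Pax3 caps, did not pass in either fit (adjusted p = 1, blocked 0.144). The part of dexamethasone or of injection in any change against control cannot be tested, because no group had either without the factors.

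Some genes of the mesoderm and endoderm lists, 15 in Pax3 caps and 21 in Pax3 and Zic1 caps, were called higher than in controls in the blocked fit. Mesendoderm cells left in the explants would raise early mesendoderm genes in general. A panel of 34 such genes, of which 1, wnt8a.L, is also among the 21 raised ones, had a median change of 0.02 in Pax3 and Zic1 caps (95% interval -0.1 to 0.18) and -0.12 in Pax3 caps (-0.22 to 0.01), where the raised genes had medians of 2.7 and 2.68. The members brightest in control caps were vegt.S (level 7.17), at -0.6 in Pax3 caps and -0.42 in Pax3 and Zic1 caps, a2m.S (7.07) at -0.79 and 0.1, vegt.L (6.64) at -0.34 and 0.25, wnt11b.L (6.2) at 0.35 and 1.87, and tbxt.S (5.74) at -1.67 and -0.8. wnt11b.L and wnt8a.L were the 2 called higher, in the blocked fit of Pax3 and Zic1 caps, and a2m.S the 1 called lower, in that of Pax3 caps. wnt8a.L was at 1.87 and 2.91, and eomes.L, at 0.03 and 2.15, did not pass. The panel was fixed after the result was seen and set against genes chosen for being raised, so its lower median was largely built in. It therefore cannot decide on such cells. They stay open as a cause, as does an effect of the factors, of dexamethasone or of injection. A response of these genes to Pax3 may be read from these values only as a hypothesis.

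Genes higher when Zic1 was added may instead answer more Pax3, since pax3.S was higher by 1.15 and 0.99 in the caps with both factors without the drug; in the drug the same probe sets differed by 0.45 and 0.52 and did not pass. The 244 probe sets higher with Zic1 in the blocked fit without the drug, by a median of 1.25, changed by a median of -0.04 (95% interval -0.12 to 0.04) under Pax3 with cycloheximide against control, in arrays not used to choose them apart from the shared fit. The 176 higher with Zic1 in the drug, by a median of 1.4, changed by 0.02 (-0.06 to 0.06) under Pax3 without it. Both medians lie below the rise with Zic1, which argues against the Pax3 level as the cause for most of the genes whose response follows the dose. Under Pax3 alone 3.7% of the 244 and 5.1% of the 176 changed by at least the median rise of their set. For those members the Pax3 level stays open. For the 244 the medians cannot decide on responses that need new protein, which the drug blocks. The drug's own effect is also in that comparison. Such responses stay open for the 244, as do a response that starts only above a threshold of Pax3 and the effect of Zic1.

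Genes higher in Pax3 and Zic1 caps with cycloheximide than in controls may owe their rise to the drug. Of 719 such probe sets 84 were also higher in caps that had no drug. Independent lists would share 2.08, but both comparisons use the same 3 control arrays. Simulated unchanged groups against simulated controls shared 0 in each of 50 runs. With nothing changed few calls could arise there, so these runs cannot show what part of the 84 the shared controls give. That 84 rose without the drug too argues against the drug as the cause of every rise over these control arrays. Of the other 635, 210 (33.1%) were called higher with than without the drug at the same factors. The 635 were set by the fit without the block, and in the blocked fit 524 probe sets were higher both without and with the drug. Of the 635, snai1.S, foxd3.L and tfap2b.L were higher without the drug in the blocked fit. For these genes a rise over control did not need the drug, though injection and dexamethasone remain. How many of the 635 did likewise was not counted. For members not called higher without the drug in either fit, the comparisons with control cannot tell the drug and the factors apart. No group had cycloheximide without the factors. Only the comparison with the drug in both groups can show a difference that came with Zic1. It did so in the blocked fit for snai1.S, which is among the 635.

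Other splits of the same samples were counted for each comparison. For comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. In each of the 8 such comparisons 1 split, the real one, gave a count as large. The real count and the highest other were 93 and 0 for Pax3 against control, 160 and 1 for Pax3 and Zic1, 822 and 0 and 1483 and 0 for the same with cycloheximide, 6 and 0 for Zic1 added, 11 and 0 for Zic1 added in the drug, and 283 and 0 and 517 and 24 for the drug in Pax3 caps and in Pax3 and Zic1 caps. With the replicate block only the 4 splits of each comparison that keep the pairing were counted, the real one among them. The real counts were 695, 1416, 4836, 6159, 363, 242, 3412 and 5344 and the highest other was 0 in each.

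For the mean Zic1 effect 1 of 100 splits, the real one, gave 164 probe sets, and the highest other gave 0. Of these splits 32 keep the pairing by replicate number, and the highest other among those gave 0 too. With the block 1 of 32 gave 1298, and the highest other 1. A share of 1 of 32 is the smallest that the paired splits can give, so chance is unlikely and not excluded. For the interaction the real count is 0, which every split must reach (100 of 100, and 32 of 32 with the block), so the splits say nothing about chance there. The highest other gave 164, and 1298 with the block, which is the split that exchanges the Zic1 labels in 1 arm and so counts the mean effect. The 2 shared rises of Zic1 in both arms were reached by 1 of 100 splits, with 0 as the highest other. Most of these splits ignore the pairing by replicate number that the samples showed, so they do not exclude chance. The splits that keep the pairing are 16, too few for a share under 0.05; the highest other of them gave 0, and with the block 1 of 16 gave the real 87 and the highest other 0. The 84 shared rises of Pax3 and Zic1 against control were reached by 3 of 100 splits and the 58 of Pax3 by 4 of 100. These splits ignore the pairing and regroup samples that differ by drug and factors, so they do not exclude chance. The highest other splits gave 205 and 123, more than the real ones, which points to a structure of the samples: in both splits the 3 samples with cycloheximide were the common group. Among the splits of Pax3 caps, the highest with samples of 1 replicate number as the common group gave 104, also more than the real 58. Among those of Pax3 and Zic1 caps the highest of this kind gave 1. With the replicate block the shared rises were 524 and 218.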
